A study of Malus domestica with 5 samples.

How the data were processed

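Small RNA libraries of apple were compared between buds of the juvenile phase (2 libraries, whose tissue label names suckers with juvenile character at the foot of the stem) and buds of the reproductive phase (3 libraries). Per the labels' protocols, small RNAs were size-selected on a gel from total RNA, ligated to adapters at both ends, copied into cDNA and amplified. The counts are whole-number read counts per feature as deposited by the authors, with no normalization. Bowtie 1.1.2 is named in the submitters' processing notes; the mismatches allowed, the treatment of reads with several matches, the genome build, the repeat annotation and the length and quality filters are not given in the sources used here. Libraries were assigned by matching column names to the sample titles.

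The table holds 430043 features: 207 named apple miRNAs, 441 candidate miRNAs in 2 series of names (172 and 269) and 429395 numbered repeats. It gives neither sequences nor lengths, so the shares of reads by length planned beforehand were not analysed here, and neither were windows along the genome. The repeats are not paired with gene or element names, and at most 2 are named in each direction. Of the 207 miRNA names, 95 match a miRNA gene name in the RefSeq gene table of apple. The sums of counts were 97283456 and 85087230 (juvenile) and 140173167, 122455352 and 123231156 (reproductive). Features with a count above 0 made up 78.2% and 74.6% of the table in juvenile, and 85.9%, 85.9% and 86.2% in reproductive libraries. Features with identical counts in all 5 libraries were frequent among members of one miRNA family, so reads with several matches appear to be counted under each match. Sums over members would count such reads repeatedly, members that share their reads cannot be told apart, and no counting interval is given because the number of reads is unknown.

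Computations were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Features entered the test with at least 10 counts in at least 2 libraries, which left 282619. Library sizes were the sums of counts times TMM factors, which were 0.676 and 0.580 in the juvenile and 1.33, 1.35 and 1.43 in the reproductive libraries. Groups were compared with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with group as the only term, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The common biological coefficient of variation was 0.0758 over features and 0.17 over families. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Normalised counts were scaled so that the geometric mean of the library factors is 1.

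miRNA families were formed from the names in the table, adding up each distinct set of counts once within a family, a choice made after the identical counts were seen. There were 44 families, of which 37 entered the test with the library factors of all features. miR2118 and miR482-5p were kept as families of their own, as the table names them, and miR2118 was placed with the siRNA triggers after its name was seen and is left out of the counts adjusted over the list alone. Family lists (age, auxin, meristem, MYB and TCP, nutrient, small RNA machinery, siRNA triggers, other conserved, anther, and fragments of tRNA and rRNA) were fixed before the data were examined. No feature carried a name of the anther list, of the tRNA and rRNA list, or of trans-acting siRNAs, so these were not tested. Lists were tested on distinct features with limma's camera (preset correlation 0.01, and estimated) and fry. The share of counts in listed families and the within-library quotients of families were compared with two-sided exact permutation tests over the 10 splits of 2 against 3 libraries, which cannot give p under 0.1. Changes of a member's share within its family were tested with edgeR's diffSpliceDGE on 42 distinct members of 15 families.

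The naming rule was fixed before the data were examined. It names every listed family tested, with full statistics for those past the threshold and for miR156 and miR172, and the 5 features with the largest fold change in each direction among those past the threshold with groups that do not overlap and at least 10 CPM in the higher group, of which 2 in each direction are printed because the repeats have no names. It also names the most abundant feature of each library. Candidates and families outside the lists were named after their values were seen.

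No library was a copy of another: within groups the counts of each pair differed by more than sampling noise (chi-square per feature 6.11 for the juvenile pair and 4.60, 7.05 and 2.50 for the reproductive pairs). The first principal component separated the groups and held 76.9% of the variance. The labels do not say that replicates came from separate trees, so p-values measure the spread between these libraries, which can be technical. Only the juvenile libraries are labelled as coming from suckers, and no library of reproductive-phase buds is, so phase and kind of shoot are not separated by the design.

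The tests were tested on simulated data made from these libraries' means and sizes. Within each simulation all entries were drawn independently and at a fixed dispersion, which was lower for members than for families. Spread that varies between entries or is shared by them was not simulated. For features of this comparison (282619), 22% of those changed 1.5-fold, 78% of those changed 2-fold and 94% of those changed 4-fold upwards were recovered, and 40% of those lowered to 0.5 of their level. For families (37), 75% of those lowered to 0.5 of their level and 78% of those raised 2-fold were recovered, and 1.70% of unchanged families were called. For member shares (42), 96% of members raised 4-fold and 80.7% of those lowered to 0.25 of their level were recovered. Of the other members, some in families with a changed member, 5.94% were called. Families and members were simulated and tested with the same library factors, so these rates leave out any error from scaling. Features were changed in sets of 50 per fold in 1 draw, far fewer than were called in the data.

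Alternatives listed before the data were examined were DESeq2, the sums of counts without TMM factors, TMM over the families, other count minimums, the replicate number as a block, leaving out each library in turn, and leaving out the 10 most abundant features from the share. Family assignment by identical sequences was not run, as it needs sequences. Collapsing identical features, adding every member, TMM over the families for single features, other settings of the list tests, the within-library quotients and the member shares were chosen after seeing the data.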

Results

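Small RNAs were counted in apple (Malus domestica) buds of the juvenile and of the reproductive phase. An apple tree raised from seed first passes through a juvenile phase in which it does not flower, and the series compares the small RNAs on either side of that transition. Both groups are titled as buds. For the 2 juvenile libraries the tissue label adds suckers with juvenile character, which are shoots growing at the foot of the stem, and for the 3 reproductive libraries it names reproductive buds alone. The deposited table gives counts for 430043 features. Of these, 207 are apple miRNAs under their mdm-miR names, 441 are candidate miRNAs and 429395 are repeats known here only by a number. The counts summed to 97283456 and 85087230 in juvenile replicates 1 and 2, and to 140173167, 122455352 and 123231156 in reproductive replicates 1, 2 and 3. Many features had the same counts as another feature in every library (274014 distinct sets of counts), and all 9 miR166 members did, so a read can stand in the table more than once. The sums are therefore not numbers of reads, and the read depth is unknown.

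The comparison of reproductive-phase with juvenile-phase buds asked which small RNAs differ between the phases. Among conserved miRNAs, miR398 and miR408, both regulated by copper supply in plants, were far lower in the reproductive libraries. The age-related miR156, which represses SPL transcription factors and holds plants in the juvenile phase, was lower in the reproductive libraries, and miR172, which represses AP2-like genes and promotes the adult phase and flowering, was higher. The auxin-related miR393 and the conserved miR1511 were higher as well. Of the 37 families with enough counts, 5 were higher and 14 lower in edgeR's quasi-likelihood test with TMM scaling. Adjusted over the list alone, 5 of the 31 tested families placed on a list in advance were higher and 12 lower. In 26 of the 37 families the TMM-normalised counts of the groups did not overlap, where exchangeable libraries, 2 against 3, would give 20%. The families share the same 5 libraries and a common scaling, so this count is not a test of the families. Over all 282619 features tested, 59591 were higher and 68558 lower in the same edgeR test. That feature test had a smaller common coefficient of variation (0.0758 against 0.17 for families). Some listed families that did not pass, and that hold a single set of counts, were called there. These were miR3627 and miR162, higher (edgeR adjusted p = 0.0066 and 0.013), and miR827 and miR403, lower (0.015 and 0.048). miR390, miR828, miR2118 and miR7122 were called in neither. Below, families pass or fail by the family test.

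How the libraries were scaled decided the direction of part of these families. TMM set the reproductive libraries 3.07-fold above the juvenile ones, while the sums of counts differed by 1.41-fold, so log2 fold changes scaled on the sums alone lie higher by about 1.12, and those scaled with TMM over the families by about 0.45. Across TMM, DESeq2, TMM over the families and the sums alone, 4 families were higher in each case (miR167, miR393, miR164 and miR1511) and 3 were lower in each case (miR398, miR408 and miR7121). For 10 families the direction depended on the scaling, and 20 had a single direction but were not past the threshold in all 4. Log2 fold changes below are from TMM, as reproductive over juvenile, with their standard errors (SE), and normalised counts are means ± SD (n = 2 juvenile and n = 3 reproductive libraries).

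**Figure D1:**
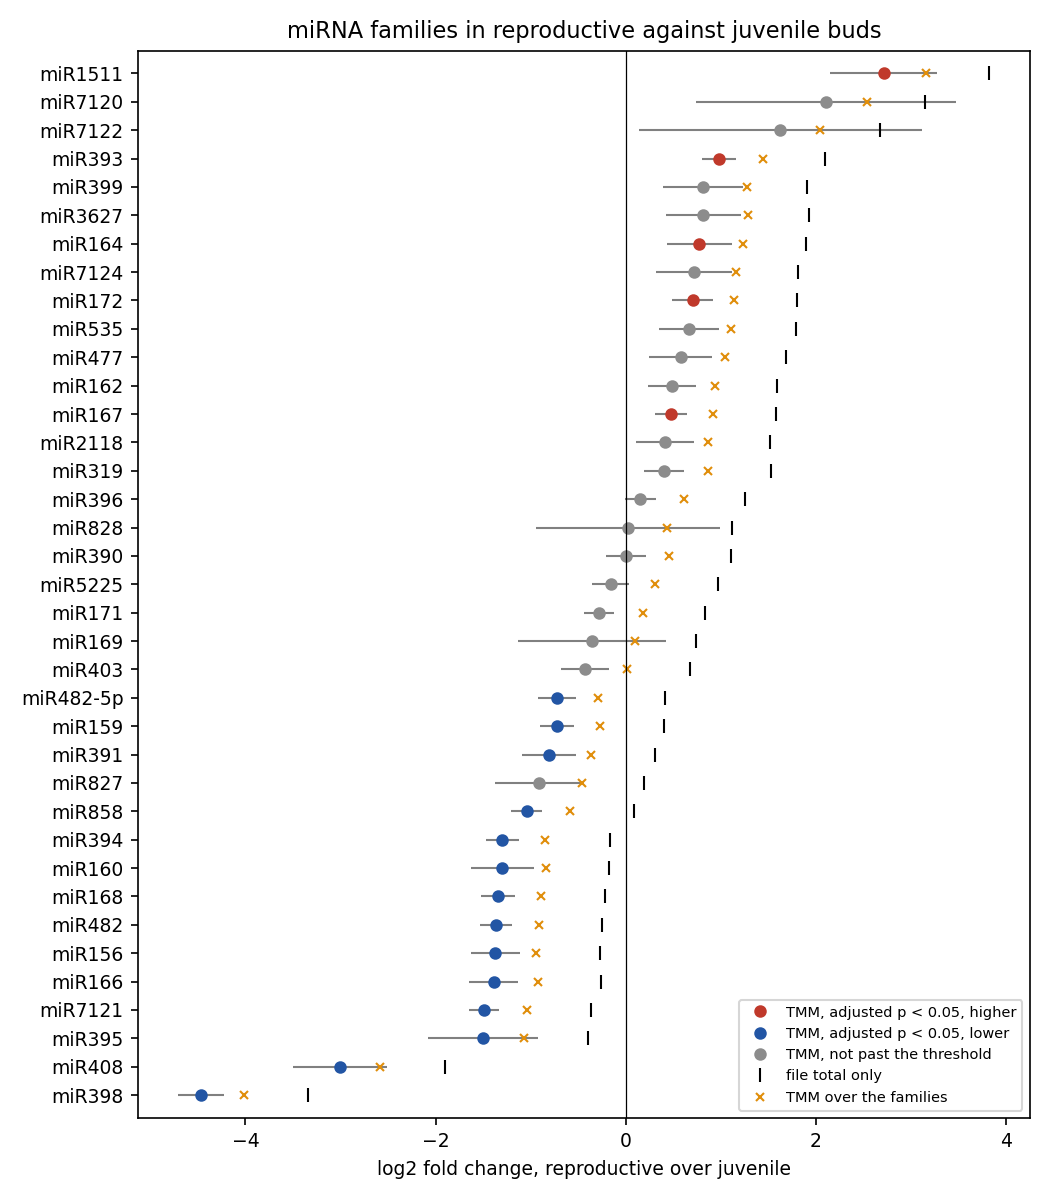
Log2 fold change of each tested miRNA family in reproductive over juvenile libraries (n = 3 and n = 2). Points are TMM estimates with standard errors as bars, coloured by edgeR adjusted p, and ticks and crosses give the same families scaled on the sums of counts and with TMM over the families. miR398 lies at -4.46 under TMM and at -3.34 under the sums, whereas miR159 moves from -0.72 to 0.41.

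Both age-related families passed the test, in opposite directions. miR156 fell 2.59-fold, from 330.25 ± 144 to 129 ± 45.1 normalised counts (log2 fold change -1.37, SE 0.25, edgeR adjusted p = 1.7e-06). miR172 rose 1.63-fold, from 313 ± 129 to 515 ± 139 (log2 fold change 0.70, SE 0.22, edgeR adjusted p = 0.0037), with overlapping groups. The quotient of miR172 over miR156 counts within a library, which no scaling can change, was 0.937 and 0.970 in the juvenile libraries and 4.55, 3.69 and 4.05 in the reproductive ones. That is a 4.28-fold difference (two-sided exact permutation p = 0.1, the smallest that 10 splits can give, and 0.125 after Benjamini-Hochberg adjustment over 5 quotients), and it was chosen after the data were seen. Taken singly, both calls were fragile: miR156 had a log2 fold change of -0.27 under the sums alone (edgeR adjusted p = 0.59) and -0.83 without juvenile replicate 1 (edgeR adjusted p = 0.13). The miR172 log2 fold change was 1.21 without juvenile replicate 1, and the call ended with DESeq2 (adjusted p = 0.052) and in edgeR without juvenile replicate 2 (log2 fold change 0.35), reproductive replicate 2 (0.57) or reproductive replicate 3 (0.63).

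**Figure D2:**
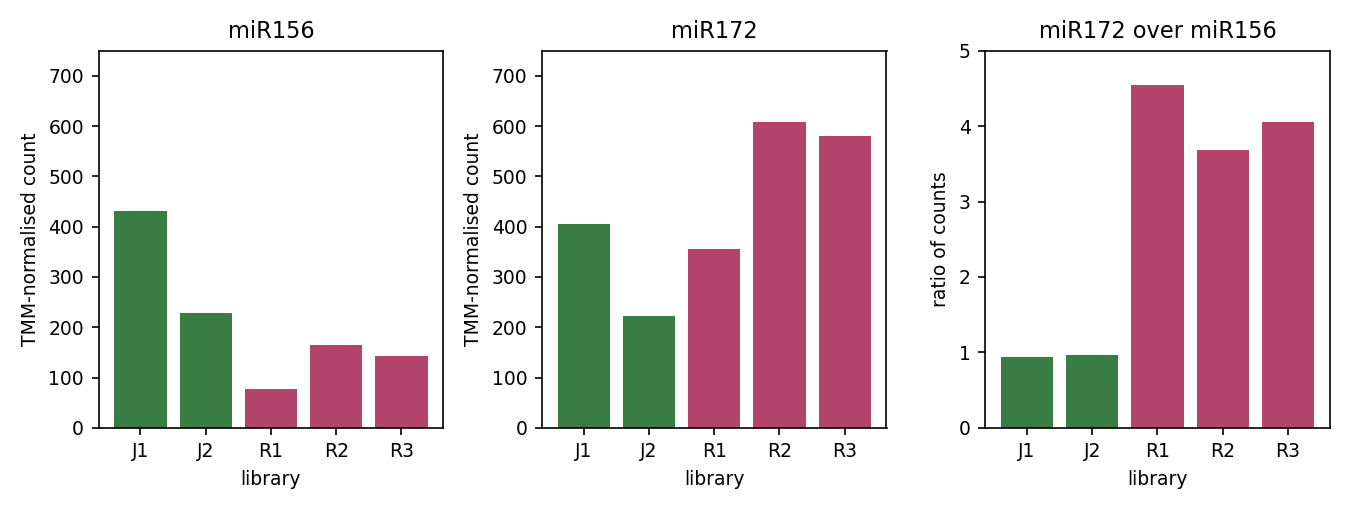
TMM-normalised counts of miR156 and miR172, and the quotient of their counts, in the 2 juvenile (J1, J2) and 3 reproductive (R1, R2, R3) libraries, one bar per library. The quotient is 0.937 and 0.970 in the juvenile libraries and between 3.69 and 4.55 in the reproductive ones, while the miR172 counts of the groups overlap.

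Of 4 auxin-related families tested, 2 rose, 1 fell and 1 did not pass. miR393, which targets the TIR1-type auxin receptors, rose 1.98-fold, from 806 ± 86.5 to 1595 ± 164 (log2 fold change 0.98, SE 0.18, edgeR adjusted p = 9.7e-07). miR167, which targets auxin response factors that activate transcription, rose 1.39-fold, from 1507 ± 201 to 2095 ± 207 (log2 fold change 0.47, SE 0.17, edgeR adjusted p = 0.012). Its members moved in opposite directions as single features under TMM. The counts shared by miR167b to miR167g rose 1.70-fold (edgeR adjusted p = 7.1e-05), and those shared by miR167h to miR167j fell 1.47-fold (0.0010). miR160, which targets repressive auxin response factors, fell 2.46-fold, from 149.8 ± 6.96 to 60.9 ± 12.1 (log2 fold change -1.30, SE 0.33, edgeR adjusted p = 0.00042). miR390, the trigger of trans-acting siRNAs against auxin response factors, had a log2 fold change of 0.00 (SE 0.21) and was higher under the sums (edgeR adjusted p = 0.0088). The miR167 call ended without juvenile replicate 2 (log2 fold change 0.34) or reproductive replicate 2 (0.41), and that of miR160 ended under the sums (-0.18).

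Of 5 families of meristem and leaf development, 1 rose, 2 fell and 2 did not pass. miR166, which targets the HD-ZIP III genes of meristem and leaf polarity, was the most abundant family and fell 2.62-fold, from 464814 ± 69567 to 177439 ± 44019 (log2 fold change -1.39, SE 0.26, edgeR adjusted p = 2.0e-06). miR394, which represses an F-box gene in the shoot meristem, fell 2.46-fold, from 29361 ± 4994 to 11948 ± 205 (log2 fold change -1.30, SE 0.17, edgeR adjusted p = 1.0e-10). miR164, which targets the CUC-type NAC genes of organ boundaries, rose 1.71-fold, from 74.5 ± 6.73 to 127 ± 7.91 (log2 fold change 0.77, SE 0.34, edgeR adjusted p = 0.049). The log2 fold change was -0.28 (SE 0.16) for miR171, which turned to 0.83 under the sums and 0.18 with TMM over the families, and 0.15 (SE 0.16) for miR396. miR396 was called higher under the sums (1.26) and with TMM over the families (0.61). miR171 was called in opposite directions, higher under the sums (edgeR adjusted p = 0.0077) and lower without reproductive replicate 1 (-0.46). Under the sums the calls of miR166 (-0.26) and miR394 (-0.16) ended, and that of miR164 ended in edgeR when any 1 of the 5 libraries was left out (log2 fold changes from 0.68 to 0.86, adjusted p from 0.053 to 0.13) or no count minimum was set (adjusted p = 0.059).

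Of 4 families that target MYB or TCP transcription factors, 2 fell and 2 did not pass. miR858, a regulator of MYB genes of flavonoid synthesis, fell 2.06-fold under TMM, from 3732 ± 683 to 1812 ± 50.1 (log2 fold change -1.04, SE 0.16, edgeR adjusted p = 1.3e-08), and stood at 0.09 under the sums. miR159, which targets GAMYB-like genes, fell 1.65-fold under TMM, from 41068 ± 5502 to 24871 ± 1005 (log2 fold change -0.72, SE 0.18, edgeR adjusted p = 0.00039), was higher under the sums (0.41) and lost its call with TMM over the families (-0.27). Its relative miR319, which targets TCP genes, had a log2 fold change of 0.40 (SE 0.21, edgeR adjusted p = 0.092) and was called higher under the sums (1.52) and with TMM over the families (0.87), and miR828 had one of 0.02 (SE 0.97). Within a library, miR319 over miR159 was 2.16-fold higher in the reproductive libraries (two-sided exact permutation p = 0.1, Benjamini-Hochberg adjusted 0.125), and miR319 over miR166 3.49-fold higher (exact permutation p = 0.1, adjusted 0.125).

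Of 6 nutrient-related families tested, none rose, 3 fell and 3 did not pass. miR398, which targets copper/zinc superoxide dismutases, fell 22.1-fold, from 892 ± 66.8 to 40.2 ± 3.71 (log2 fold change -4.46, SE 0.24, edgeR adjusted p = 1.7e-34). miR408, which targets the blue copper protein plantacyanin and laccases, fell 8.03-fold, from 75.6 ± 20.5 to 9.59 ± 5.99 (log2 fold change -3.01, SE 0.50, edgeR adjusted p = 1.1e-07). The sulfate-related miR395 fell 2.83-fold, from 34.3 ± 16.5 to 12.5 ± 4.30 (log2 fold change -1.50, SE 0.58, edgeR adjusted p = 0.022). The phosphate-related miR399 and miR827 had log2 fold changes of 0.82 (SE 0.42) and -0.91 (SE 0.46), and miR169 one of -0.36 (SE 0.78). miR399 was called higher under the sums (1.91), with TMM over the families (1.28) and without juvenile replicate 1 (1.78), and stood at 0.32 without juvenile replicate 2. miR827 was called lower with DESeq2 (adjusted p = 0.049) and turned to 0.19 under the sums. miR169 turned to 0.74 under the sums, to 0.10 with TMM over the families and to 1.18 without juvenile replicate 1. The miR395 call ended under the sums (-0.40), with TMM over the families (-1.07), and without juvenile replicate 1 (-0.87) or reproductive replicate 1 (-1.24), 2 (-1.72) or 3 (-1.54).

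Of 3 families that target the small RNA machinery, 1 fell and 2 did not pass. miR168, which targets ARGONAUTE1, fell 2.54-fold, from 1261 ± 86.0 to 496 ± 23.2 (log2 fold change -1.34, SE 0.18, edgeR adjusted p = 1.9e-10), a call that ended under the sums (-0.22). miR162, which targets DICER-LIKE1, had a log2 fold change of 0.49 (SE 0.26) and was called higher under the sums (1.59), with TMM over the families (0.94) and without juvenile replicate 1 (0.80). The log2 fold change of miR403, which targets ARGONAUTE2, was -0.43 (SE 0.25) and turned to 0.68 under the sums and 0.02 with TMM over the families. Of 4 families that trigger phased secondary siRNAs, only miR482, which targets NBS-LRR resistance genes, passed, falling 2.58-fold from 31316 ± 46.3 to 12157 ± 793 (log2 fold change -1.37, SE 0.17, edgeR adjusted p = 2.2e-11, and -0.25 under the sums). As single features under TMM, miR482b and miR482c fell 2.90-fold and 2.67-fold, and miR482a-3p was not called. The rare miR482d rose 2.52-fold (edgeR adjusted p = 0.0064). Log2 fold changes were 0.41 (SE 0.30) for miR2118 and 0.81 (SE 0.39) for miR3627, neither past the threshold under TMM. Both were called higher under the sums (1.52 and 1.92) and with TMM over the families (0.86 and 1.28), miR3627 also with DESeq2 (adjusted p = 0.032) and in edgeR when every member was added (adjusted p = 0.028), and miR7122 had few counts in either group (1.70 ± 2.40 and 6.24 ± 1.97 normalised counts).

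Of 4 other conserved families, miR1511 rose 6.56-fold, from 10.2 ± 4.82 to 70.4 ± 23.6 (log2 fold change 2.71, SE 0.56, edgeR adjusted p = 1.5e-05), and stood at 3.35 without juvenile replicate 1. miR391, a relative of miR390, fell 1.75-fold under TMM, from 214 ± 17.4 to 122 ± 13.1 (log2 fold change -0.81, SE 0.28, edgeR adjusted p = 0.011), stood at 0.30 under the sums, and lost its call with TMM over the families (-0.36) and without juvenile replicate 1 (-0.72) or reproductive replicate 3 (-0.72). miR477 and miR535 had log2 fold changes of 0.58 (SE 0.33) and 0.66 (SE 0.32) and did not pass under TMM. Both were called higher under the sums (1.69 and 1.79) and with TMM over the families (edgeR adjusted p = 0.012 and 0.0081), and miR535 also with DESeq2 (adjusted p = 0.032). Of 5 tested families outside the lists fixed in advance, 2 fell, and these are named after their values were seen. miR7121 fell 2.82-fold (log2 fold change -1.49, SE 0.16, edgeR adjusted p = 1.7e-14). miR482-5p, a single feature (miR482a-5p) counted apart from miR482, fell 1.65-fold under TMM (log2 fold change -0.72, SE 0.20, edgeR adjusted p = 0.00094). It was higher under the sums (0.41) and lost its call with TMM over the families (-0.29), and its log2 fold change was -0.57 without juvenile replicate 2.

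Tested as lists on single features under TMM, no group stood apart from all other features by a directional shift. Members that move oppositely, as miR156 and miR172 of the age list did, offset each other in such a test. For changes in either direction, limma's fry gave adjusted p from 0.00013 (nutrient) to 0.018 (age) over the 9 lists. That version of fry does not compare a list with other features either. In limma's camera 0 of 9 lists passed after Benjamini-Hochberg adjustment, with 1 list, the nutrient group, at an unadjusted p under 0.05 (median log2 fold change -1.06, camera adjusted p = 0.40, and adjusted p = 0.98 with an estimated correlation). This count depended on the scaling: with the preset correlation, limma's camera placed the nutrient list below other features with TMM over the families (adjusted p = 0.00040) and 4 lists under the sums, which were the nutrient (adjusted p = 5.9e-09), age (0.027) and siRNA trigger (0.041) lists and all listed miRNAs (1.1e-05). In limma's fry, which asks whether the members of a list move one way on balance and not whether they differ from other features, the nutrient list moved downwards under TMM (adjusted p = 0.017) and the sums (0.047), and not with TMM over the families (0.11). Under the sums, limma's fry called 6 other lists upwards (adjusted p from 0.00085 to 0.047), among them the siRNA triggers and all listed miRNAs, which camera placed below other features under the same scaling. The small RNA machinery list moved downwards in limma's fry under TMM (adjusted p = 0.033), a call that ended in a fit of named miRNAs alone (0.10) and turned upwards without passing under the sums (0.094) and with TMM over the families (0.86). The age and siRNA trigger lists had positive medians under TMM (0.35 and 0.46) while camera gave them a downward direction. Under the sums, where camera called both lists downwards, their medians (1.23 and 1.56) lay above the median of all features in that test (1.13). Camera's direction therefore does not describe the typical member of these lists. With every member counted, all named miRNAs held 2.52% and 2.66% of the juvenile counts and 2.90%, 2.19% and 2.08% of the reproductive ones. For the listed families each distinct set of counts was taken once and divided by the sum over all features. On that measure they made up 0.364% ± 0.00813 (SD, n = 2) in juvenile and 0.403% ± 0.0613 (SD, n = 3) in reproductive libraries. The difference of 0.0388 percentage points was smaller than the SD of the reproductive libraries and larger than that of the juvenile ones (two-sided exact permutation p = 0.6). The difference was 0.0035 without reproductive replicate 1, and 0.0171 with the 10 most abundant features left out of the counts (two-sided exact permutation p = 1).

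The most abundant features took a smaller part of the reproductive libraries. The 100 most abundant features held 53.8% and 56.8% of the counts in the juvenile libraries, and 36.2%, 34.8% and 32.8% in the reproductive ones. The most abundant feature in each library was repeat_1289403, at 2.46% and 2.64% of the juvenile counts and 1.65%, 1.45% and 1.35% of the reproductive ones. Under TMM the median log2 ratio of reproductive over juvenile means went from 0.27 for features of 10 to 100 normalised counts to -0.20 for 100 to 1000, -0.69 for 1000 to 10000, -1.58 for 10000 to 100000 and -1.80 above 100000. The abundant families that fell stand beside these medians: miR166 above 100000 counts had -1.39. Between 10000 and 100000, miR394, miR482, miR159 and miR482-5p had -1.30, -1.37, -0.72 and -0.72, while miR319 in the same range had 0.40.

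**Figure D3:**
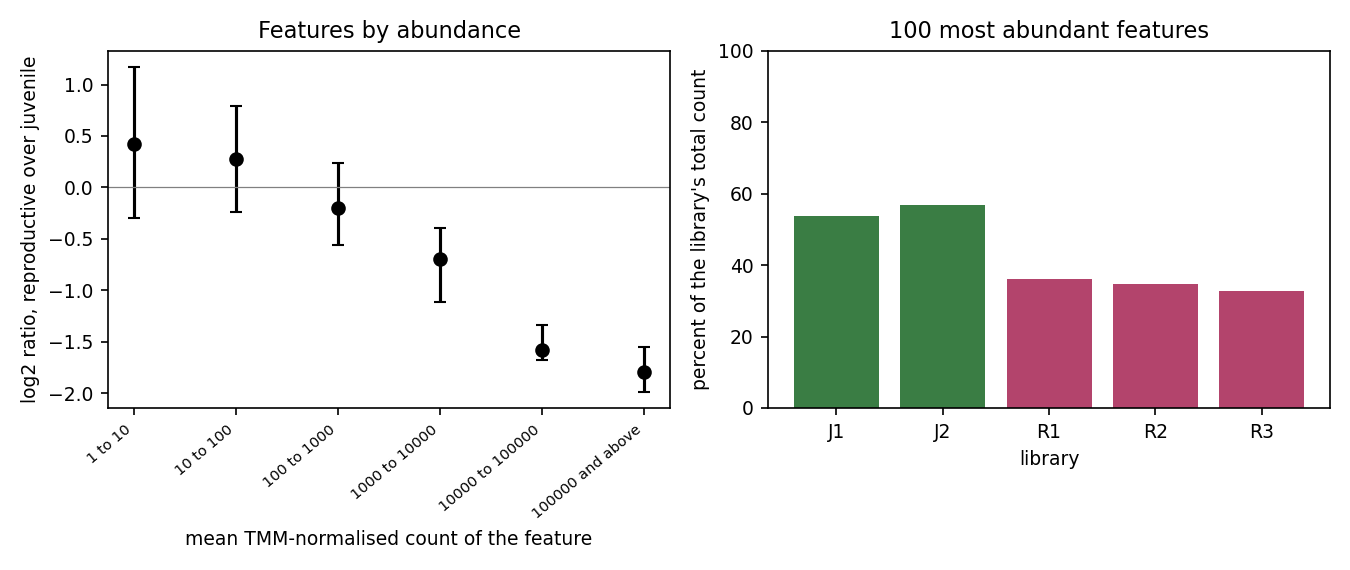
Left, median log2 ratio of reproductive over juvenile mean TMM-normalised counts for distinct features grouped by mean normalised count, with quartiles as bars. Right, percent of each library's counts held by the 100 most abundant features, from 53.8% and 56.8% in the juvenile libraries (J1, J2) to 32.8% in reproductive replicate 3 (R3).

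Candidate miRNAs, taken one by one, were mostly lower in the reproductive libraries under TMM. As a class their share of the summed counts was larger there (0.067%, 0.062% and 0.070%) than in the juvenile libraries (0.030% and 0.032%). This share counts every candidate, including those with identical counts, and leans on novelMiR_3279. Its raw counts were 7671 and 7815 in the juvenile and 39004, 30459 and 35501 in the reproductive libraries. The next most abundant distinct candidate tested, novelMiR_4508, had 1080 and 774 against 2174, 1160 and 1098. Of 122 distinct candidates tested, 8 rose, 50 fell and 64 did not pass (median log2 fold change -0.76), against 36 higher and 23 lower under the sums and 12 higher and 38 lower with TMM over the families. Named after their values were seen, novelMiR_406 fell 8.84-fold, from 1098 ± 247 to 123 ± 26.2 normalised counts (log2 fold change -3.14, SE 0.15, edgeR adjusted p = 4.9e-10). By contrast, novelMiR_4248 rose 5.55-fold, from 4.81 ± 0.405 to 27.4 ± 4.98 (log2 fold change 2.47, SE 0.49, edgeR adjusted p = 0.00065). Its raw counts were only 3 and 2 in the juvenile libraries, against 40, 37 and 52 in the reproductive ones. The number of candidates that rose was 5 without juvenile replicate 1 and 2 without juvenile replicate 2.

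Repeats made up most of the tested features and changed in both directions. Of all 282619 features tested, 59591 were higher and 68558 lower under TMM in edgeR, so 46.5% of the calls were higher. The split was 97.1% higher under the sums alone (235325 higher and 6957 lower), 84.7% higher with TMM over the families (104163 and 18879) and 37.8% higher with DESeq2 (35951 and 59181). Among repeats that passed the naming rule, repeat_1135880 rose 2.67-fold, from 652 ± 80.4 to 1750 ± 80.0 normalised counts (log2 fold change 1.42, SE 0.10, edgeR adjusted p = 1.7e-08), and repeat_1135461 had a log2 fold change of 1.22 (SE 0.11). In the other direction, repeat_1260178 fell 7.02-fold, from 4156 ± 717 to 591 ± 68.0 (log2 fold change -2.81, SE 0.12, edgeR adjusted p = 4.9e-10), and repeat_1258320 had a log2 fold change of -2.80 (SE 0.10). Without juvenile replicate 2 the number of higher features was 31260.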

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

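TMM over the families for single features, the other scalings of the list tests, the adding of every member, and the alternatives for quotients and member shares were chosen after seeing the data. Of 19 called families, 12 kept call and direction when each library was left out, and 4 (miR393, miR398, miR408 and miR7121) did so under every alternative that tested them. Scaling on the sums of counts gave 235325 higher and 6957 lower features, 36 higher and 23 lower candidates, 20 higher and 3 lower families and 4 lists past camera's threshold, the reproductive factors being smaller by construction. It turned the log2 fold change of miR159 to 0.41, miR169 to 0.74, miR171 to 0.83, miR391 to 0.30, miR403 to 0.68, miR482-5p to 0.41, miR5225 to 0.96, miR827 to 0.19 and miR858 to 0.091. TMM over the families gave 104163 higher and 18879 lower features, 14 higher families and 1 list past camera's threshold, and turned miR169 to 0.10, miR171 to 0.18, miR403 to 0.015 and miR5225 to 0.30. DESeq2 gave 35951 higher features and 4 higher candidates, and miR390 stood at -0.018; the cause was not tested. With at least 50 counts, 3 candidates were higher and 22 lower, among fewer tested. Adding every member moved the log2 quotient of miR172 over miR156 from 2.10 to 2.28.

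Leaving out each library gave 31260 to 65411 higher features, 2 to 9 higher candidates and 2 to 7 higher families. The 2 higher families were found without juvenile replicate 2 and without reproductive replicate 2, with 3 without reproductive replicate 3. Log2 fold changes ranged from -0.96 to 1.18 for miR169, from -0.26 to 0.34 for miR390, from -0.0050 to 0.33 for miR396 and from -0.20 to 0.32 for miR828, none of them past the threshold. Lower families numbered 11 to 14, and the miR172 over miR156 difference ranged from 2.02 to 2.17. The lone juvenile library left in these fits is assumed to vary like the reproductive ones. Families of few counts had wide errors, with SE 0.97 for miR828, 0.78 for miR169 and 1.49 for miR7122.

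With the replicate number as a replicate block, 46806 features were higher and 55396 lower, and 2 families higher and 11 lower. The 6 families that lost their call kept their direction. Their log2 fold changes were 2.45 (miR1511), 0.72 (miR164), 0.62 (miR172), -1.47 (miR160), -0.74 (miR391) and -1.55 (miR395). Only 2 numbers are shared between the groups, and deviations of same-numbered libraries correlated at -0.13 and -0.04, which gives no sign of pairing. The deviations of the 2 juvenile libraries are mirror images of each other, so these correlations cannot exclude pairing.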

Other observations

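All tests of this part were chosen after the results they concern were seen. Members of one family did not always move together. Within miR398, miR398a made up 7.34% ± 0.153 of the family's counts in juvenile (SD, n = 2) and 48.9% ± 3.47 in reproductive libraries (SD, n = 3), as the counts shared by miR398b and miR398c fell 39.8-fold and those of miR398a 3.29-fold. The share of miR319c in the TCP-related miR319 family went from 0.0603% to 0.293%, that of miR171i in the GRAS-related miR171 family from 1.19% to 4.40%, and that of miR482d in the miR482 family from 0.0742% to 0.512%. Raw counts of these members in the juvenile libraries were low: 24 and 16 (miR319c), 32 and 14 (miR171i), and 18 and 7 (miR482d). In the other direction, miR167j went from 31.0% to 15.0% of miR167 and miR393f from 2.14% to 0.635% of miR393. miR393f had raw counts of 11 and 7 in the juvenile and 24, 14 and 11 in the reproductive libraries. By edgeR's diffSpliceDGE, 9 of 42 distinct members in 7 of 15 families had a changed share after Benjamini-Hochberg adjustment, with 7 to 12 when each library was left out. A factor per library cancels in a share within a family, so these shares do not depend on the scaling. Members with identical counts cannot be separated.

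The first pattern weighed is the lower level of abundant features in the reproductive libraries. If the 100 most abundant features alone caused the difference between scalings, leaving them out would bring the log2 difference of the sums to that of TMM (1.62). It went from 0.50 with all features to 1.05 without them, so these features account for part of the gap and not all of it. Above 100000 normalised counts there were 130 features, and 114 from 10000 to 100000. The cut therefore left abundant features in, and a somewhat larger set of them is not argued against. A wider mix of repeat-derived small RNAs in reproductive buds, and a technical difference between the preparations of the groups, may both underlie it, and no value here separates them.

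The second pattern weighed is the fall of miR398 and miR408. Among the 4 scalings run, the value nearest to 0 was -1.90 (miR408, under the sums), so the choice among these scalings does not account for the fall. Both families were singled out after they were seen to be lower in all 4, so this is not an independent test of scaling. The trend with abundance is argued against, since the nearer of both families lay at -3.28 from the median of features of its abundance. Both respond to copper supply, so a difference in copper status between the juvenile-phase and reproductive-phase buds is a candidate explanation. It predicts a fall of the copper-regulated miR397 too, but miR397 had 11 counts over all 5 libraries, so this stays open, as do the phase itself and the sucker origin given for the juvenile buds.

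miR319 over miR166 and miR393 over miR160 were 3.49-fold and 4.93-fold higher in the reproductive libraries, each with a two-sided exact permutation p = 0.1, the smallest that 10 splits can give, and 0.125 after Benjamini-Hochberg adjustment over 5 quotients, so neither passes. The quotient of miR398 over miR408 differed by a log2 value of -1.28 (two-sided exact permutation p = 0.3). That last value was -0.79 without reproductive replicate 2 and -1.94 without reproductive replicate 1.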
